A study of Mus musculus with 9 samples.

How the data were processed

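Total RNA from hearts of C57BL/6 mice aged 24 hours, 7 days and 10 weeks was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 3 arrays per age and 9 in all. The deposited table holds 1 log2 intensity per feature and array. Per the submitters' processing notes MAS5 5.0 was used; the summary of probes and the normalization between arrays are not given in the sources used here. The values run from 1.853 to 13.583. The highest lies above 11.09, the highest natural log of a 16-bit scanner value, so the log was taken to base 2. The medians of the 9 arrays lie within 0.05 of each other, under the limit of 0.1 set before the data were examined, and the values were used as deposited. The table has no detection flags, so a difference to or from a dim signal can be too small. An array has no sequencing depth; with 3 arrays per age and 6 residual degrees of freedom, the precision of a gene's difference is given by its standard error.

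The table holds 35556 features. Of these 23410 are listed in the platform table, 21789 with 1 gene symbol and 1621 with several, and 12146 are not listed. Symbols were matched by Entrez id for 21698 of the features with 1 symbol, and 91 had no match and kept the platform's name. Features with 1 symbol were kept, and for the 999 genes with several such features the one with the highest mean was used, which left 19938 genes. No genome build is named in the platform table, so no coordinates were used.

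Groups came from the age in the sample labels, and 3 comparisons were made: 7-day against 24-hour, 10-week against 7-day and 10-week against 24-hour. A linear model with 1 mean per age was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend. P-values were adjusted by the Benjamini and Hochberg method over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Counts at a fold of at least 2 (a log2 difference of 1 or more) are given beside them. Time courses came from crossing the calls of both steps. The shared 7-day arrays were weighed by simulating groups without change 100 times. Tables and tests were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

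Gene lists were written from general knowledge of their functions before the data were examined. They cover mitosis, DNA replication, cell cycle inhibitors, mature and immature cardiomyocyte genes, cardiac transcription factors, extracellular matrix, imprinted growth genes, antigen presentation and interferon, oxidative phosphorylation, the TCA cycle, fatty acid oxidation, glycolysis, metabolic transcription factors, the circadian clock, antioxidant defence, Hippo YAP targets, ribosome biogenesis and RNA splicing regulators of muscle. Marker lists cover fibroblasts, endothelium, mural cells (smooth muscle and pericytes), macrophages, T cells, thymocytes, B cells, neutrophils, erythroid cells, glia and nerve, epicardium and mesothelium, atrium, ventricle, skeletal muscle, brown fat, white fat, lung and liver and plasma proteins; sex-linked genes were read per array. Members without a feature of a single symbol were not tested, among them Ccnb1, H19, Cpt1b, Cdkn1a and Gapdh. Lists share members, for example Myl7 and Myl4 in the atrial and the immature lists and Lum in the matrix and the fibroblast lists. The list of imprinted growth genes also holds fetal growth genes that are not imprinted, such as Igf2bp1, Igf2bp3 and Hmga2. Each list with at least 5 tested genes was tested with camera, limma's set test, at a preset correlation of 0.01 between genes and again with the correlation estimated per list. These p-values were adjusted over all 111 tests. The calls of a list are also given with p adjusted over the list alone.

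The text names genes by a rule set before the data were examined. In each comparison these are the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05 whose groups do not overlap and whose higher mean lies above the median of all tested genes (5.57). To these the rule adds, per list and comparison, up to 4 members with the largest absolute log2 difference among those with adjusted p under 0.05, or the largest where fewer pass. It also adds the 5 genes with the largest smaller step among those that moved the same way in both steps, 5 per direction among those that turned, and a fixed set of heart, growth and metabolic genes. Any gene outside the rule is marked in the text.

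The fits were tested on simulated data for 19938 genes with known changes. With 50 genes per size, 78%, 76% and 80% of genes changed by 0.5 on the log2 scale were recovered in the comparisons in that order, and 98%, 98% and 100% of those changed by 1. Of the calls 5.05%, 2.60% and 5.03% were false. For the set tests, the circadian clock list alone was shifted, by 0.5, in 2 comparisons. Both of these tests were called, and 0 of 109 others. The simulated genes varied independently, so this does not measure false calls among correlated genes. In these simulations and those of the shared 7-day arrays, every array of a gene had the same spread. The median SD of the measured genes was 0.0675 at 24 hours, 0.0697 at 7 days and 0.1003 at 10 weeks. The rates therefore do not cover a spread that differs between ages.

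Alternatives chosen before the data were examined were quantile normalization, centring each array on its median, leaving out the 25% or the 50% of genes with the lowest signal, no intensity trend, a robust variance prior, array weights, only the 6 arrays compared, the replicate number as a replicate block, leaving out each array in turn, the mean of a gene's probes, all probes with 1 symbol, an adjusted p under 0.01 and an estimated correlation in the set tests. A pseudocount was planned only for linear values and does not apply to log2 values. Features with several symbols or absent from the platform table were left out of the comparisons, since they name no single gene.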

Results

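Heart muscle of C57BL/6 mice, an inbred laboratory strain, was profiled on Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with a set of short probes. Hearts were taken 24 hours, 7 days and 10 weeks after birth, and each age is represented by 3 arrays of total RNA. The series asks how transcript levels of the heart differ between the newborn, the 7-day-old and the 10-week-old mouse. Each array gave a log2 signal for 35556 features, and 19938 named genes entered the comparisons. The labels do not say that the replicates of an age came from separate animals, so every p-value here measures only the spread between these samples. The brown fat gene Ucp1 measured 4.30, 11.23 and 9.27 on the 7-day replicates, and the atrial gene Myl7 4.70, 8.43 and 7.52 on the 10-week ones. At 24 hours the Y-linked gene Eif2s3y measured 7.07, 7.71 and 6.28, and Xist 9.10, 8.30 and 9.37. These values argue against repeat arrays of 1 RNA. Each 24-hour and 7-day array held both Eif2s3y (6.06 to 7.71) and Xist (8.26 to 9.56). That argues against 1 animal per array at these ages. Whether a 10-week array holds 1 animal or a pool is not known. An array has no read depth, and 3 arrays per age limit the precision.

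Arrays of the same age resembled each other closely. Pearson's r over genes, which are not independent replicates, ran from 0.997 to 0.998 within the 24-hour group, from 0.995 to 0.998 within the 7-day group and from 0.994 to 0.996 within the 10-week group. It was lower between 24 hours and 7 days, at 0.990 to 0.993, and lower still between 24 hours and 10 weeks, at 0.960 to 0.963. The first principal component held 76.5% of the variance and set the 10-week arrays, with scores of 47.19 to 49.93, apart from the younger ones, with scores of -30.13 to -17.36.

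**Figure D1:**
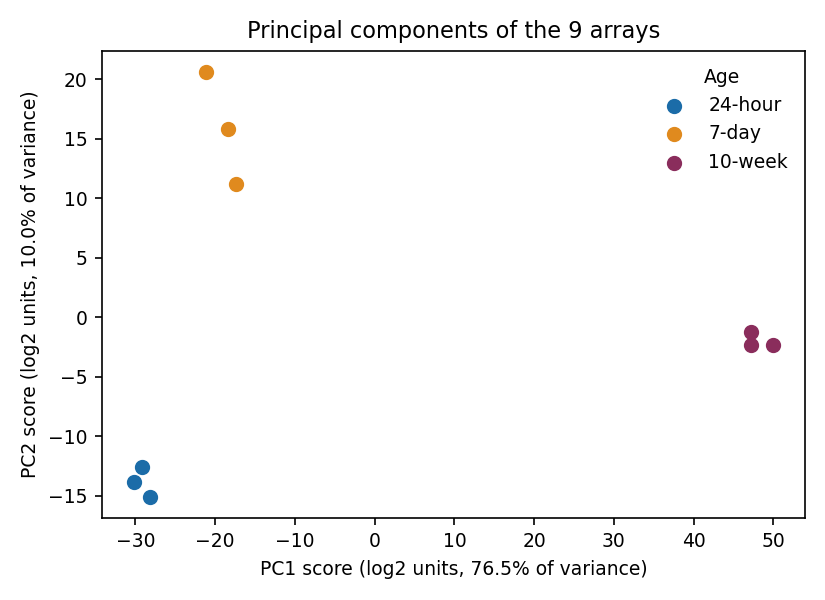
Scores of the 9 arrays on the first principal component (horizontal axis, log2 units, 76.5% of variance) and the second (vertical axis, log2 units, 10.0% of variance), 1 point per array, coloured by age. The 24-hour and 7-day arrays separate on the second component, and the 10-week arrays lie far from both on the first.

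Genes of other tissues and sex-linked genes differed between arrays of the same age. Ucp1, the uncoupling protein of brown fat, measured 4.30, 11.23 and 9.27 (log2) on the 7-day replicates 1, 2 and 3, and 3.92 to 4.27 on each of the other arrays. The fat hormone gene Adipoq measured 3.91, 7.71 and 5.33 on the same 7-day arrays. A pair of genes looked up after the values were seen stood apart too. The liver gene Alb measured 3.89, 7.81 and 3.78 on the 7-day replicates and 5.27, 4.16 and 6.04 on the 24-hour ones. The airway gene Scgb1a1 measured 6.83 on 7-day replicate 2 and 5.83 on 24-hour replicate 1, and 2.49 to 2.76 on the others. The Y-linked gene Eif2s3y lay between 6.06 and 7.71 on the 24-hour and 7-day arrays and between 2.87 and 3.30 on the 10-week arrays, while Xist, the transcript of the inactive X chromosome, lay between 8.26 and 9.56 on all 9. The atrial myosin light chain gene Myl7 measured 4.70, 8.43 and 7.52 on the 10-week replicates 1, 2 and 3, against 10.27 to 11.37 on the younger arrays.

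**Figure D2:**
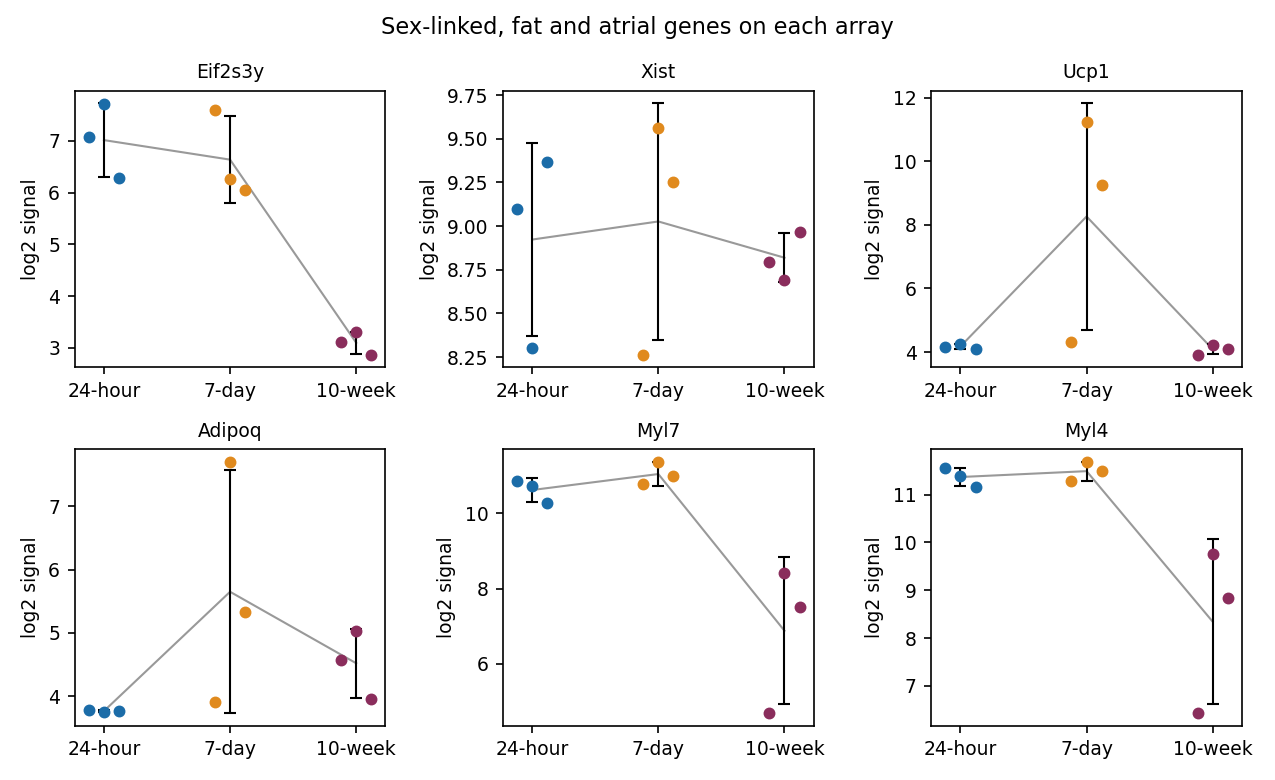
Log2 signal (vertical axes) of sex-linked (Eif2s3y, Xist), fat (Ucp1, Adipoq) and atrial (Myl7, Myl4) genes at the 3 ages (horizontal axes). Points are single arrays, black bars the mean ± SD (n = 3), and grey lines join the means; Ucp1 reached 11.23 on 7-day replicate 2, and Eif2s3y did not exceed 3.30 on any 10-week array.

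The first comparison asks what changed in the first week. Between 24 hours and 7 days the slow heavy chain of myosin, Myh7 (probe set 10419934), fell 8.54-fold, from a log2 signal of 12.26 ± 0.15 to 9.16 ± 0.28 (SD, n = 3 per age; limma's test, adjusted p = 2.01e-06). Myh6, the faster heavy chain, measured 12.78 ± 0.02 and 12.71 ± 0.06 and did not pass the test (adjusted p = 0.347). Of 19 imprinted and fetal growth genes 13 fell, among them Igf2, which went from 12.04 ± 0.05 to 11.32 ± 0.07. Of the macrophage markers 11 of 15 and of the fibroblast markers 8 of 15 were higher at 7 days, among them Lyz2, which rose from 7.28 ± 0.03 to 8.37 ± 0.13, and Lum, which rose from 8.16 ± 0.19 to 9.61 ± 0.15.

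Among genes above the median signal whose groups did not overlap, Tuba8, an alpha-tubulin, had the largest rise of the first week. It went from 6.20 ± 0.21 to 8.80 ± 0.19 (difference 2.60 ± 0.13 SE, adjusted p = 5.92e-06). Pcolce2, which enhances procollagen processing, rose by 2.44, the integrin subunit Itgb6 by 2.18, and the retinoid X receptor Rxrg by 2.15. The secretoglobin Scgb1c1 rose by 2.15, the secreted protein gene C1qtnf9 by 2.10 and Vtn, which encodes vitronectin, by 2.03. Gpd1, a glycerol-3-phosphate dehydrogenase, was 2.04 higher (adjusted p = 0.0149), but its 7-day signals were 7.47, 9.74 and 8.17, the highest on the array with the most Ucp1. Its difference was 2.01 without 24-hour replicate 1 and 1.94 without 24-hour replicate 2, and neither passed the test; nor did it with a robust variance prior (adjusted p = 0.0528) or with only the 6 arrays compared (0.0561). After Myh7, the largest falls were those of Bex4 (by 1.91 on the log2 scale), Hey2, a Notch-responsive transcription factor of the ventricle (by 1.86), Gm36028 (by 1.84) and the glycolytic enzyme gene Aldoc, which fell by 1.70. The metallothionein gene Mt2 fell by 1.66, the growth factor gene Bmp7 by 1.65 and Hif3a, of the hypoxia-inducible factor family, by 1.62.

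In the list of imprinted and fetal growth genes 6 of the 19 did not pass in the first week, and 13 fell when adjusted over the list alone. Dlk1 fell by 1.41 on the log2 scale, the RNA-binding protein genes Igf2bp3 and Igf2bp1 by 1.32 each, and Plagl1 by 1.23. The list as a whole lay lower than other genes in camera, limma's set test (adjusted p = 6.2e-14, and adjusted p = 0.0595 with an estimated correlation). Immature cardiomyocyte genes followed, with 6 of 20 lower and none higher (6 adjusted over the list alone; camera adjusted p = 2.68e-04, and adjusted p = 0.231 with an estimated correlation). Beside Myh7 these included Bex1, which fell by 1.56, the calsequestrin gene Casq1, by 1.53, and Tnni1, the fetal troponin I, by 0.72. Among 20 cardiac transcription factors, 8 fell and none rose (11 adjusted over the list alone; camera adjusted p = 5.56e-08, and adjusted p = 0.0893 with an estimated correlation), Gata6 by 0.64 and Irx4 by 0.64. That count was 4 or 5 when any 1 of the 24-hour or 7-day arrays was left out. It was 5 without 24-hour replicate 1 or 7-day replicate 2 and 4 without each of the others. The list median was -0.197 with all arrays and -0.23 without 7-day replicates 2 and 3 together. Of 25 mature cardiomyocyte genes, 7 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0222, and adjusted p = 0.456 with an estimated correlation). The mitochondrial creatine kinase gene Ckmt2 rose by 0.88 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 0.64. The camera p of this list was 0.0555 without 7-day replicate 3, and its count of falls was 2 without 24-hour replicate 2 or 24-hour replicate 3.

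Of 33 extracellular matrix genes, 11 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 9.98e-07, and adjusted p = 0.445 with an estimated correlation). Mfap5 rose by 1.62, Lum by 1.45 and Mfap4 by 1.42, while the fibrillin gene Fbn2 fell by 1.00 on the log2 scale. Of 15 fibroblast markers 8 rose and none fell (12 adjusted over the list alone; camera adjusted p = 5.0e-11, and adjusted p = 0.177 with an estimated correlation), Dpt by 1.24. Of 10 markers of smooth muscle and pericytes 4 rose (6 adjusted over the list alone; camera adjusted p = 3.88e-05, and adjusted p = 0.142 with an estimated correlation), Rgs5 by 1.30 and Rgs4 by 0.97. The brown fat transcripts of 7-day replicates 2 and 3, and the liver and airway transcripts of replicate 2, belong beside these lists. Without those arrays, 3 matrix genes were higher and 2 lower with a list median of 0.06, 5 fibroblast markers were higher with a median of 0.49, and 4 mural markers were higher with a median of 0.18; with all arrays the medians were 0.32, 0.69 and 0.43. Without 7-day replicate 2 alone, 3 matrix genes were lower. Of 7 brown fat genes 2 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.352 with an estimated correlation; camera adjusted p = 0.0576 without 7-day replicate 2). The number higher was 0 without 24-hour replicate 1, 1 without 24-hour replicate 2 or 3, 7-day replicate 3 or 10-week replicate 1, 4 without 7-day replicate 1 and 3 without 7-day replicate 2, and the number lower was 0 without 24-hour replicate 2; without 7-day replicates 2 and 3 both were 0.

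Macrophage markers were higher at 7 days in 11 of 15 cases and lower in 1, and the counts were the same when adjusted over the list alone (camera adjusted p = 2.76e-09, and adjusted p = 0.136 with an estimated correlation). Without 7-day replicates 2 and 3 the median of this list went from 0.53 to 0.435. That of the mitosis list went from -0.182 to -0.185 and that of the DNA replication list from 0.188 to 0.179. Besides Lyz2 the F4/80 gene Adgre1 rose by 1.09 and Mrc1 by 0.62; the 1 lower marker was Lyve1, by -0.81, which did not pass without 24-hour replicate 1 (-0.74), 24-hour replicate 2 (-0.78), 7-day replicate 1 (-0.70) or 7-day replicate 3 (-0.87). Of 29 mitosis genes 5 fell (5 adjusted over the list alone; camera adjusted p = 4.30e-04, and adjusted p = 0.543 with an estimated correlation), among them Ccnb2, by 0.62 on the log2 scale, and Kif20a, by 0.61. Without 24-hour replicate 3 the camera p of this list was 0.106, and 2 mitosis genes fell without that array or without 7-day replicate 1, 2 or 3. Of 30 DNA replication genes 4 rose (4 adjusted over the list alone; camera adjusted p = 1.99e-04, and adjusted p = 0.458 with an estimated correlation), with Pcna at 9.15 ± 0.08 and 9.59 ± 0.06. The proliferation marker Mki67 measured 9.36 ± 0.19 and 9.35 ± 0.07 (adjusted p = 0.988). In the glycolysis list 3 of 21 genes rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.0247, adjusted p = 0.445 with an estimated correlation, and 0.0848 without 24-hour replicate 3), with the glucose transporter gene Slc2a1 falling by 0.99 and the hexokinase gene Hk2 rising by 0.57.

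Of 19 antigen presentation and interferon genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0366, and adjusted p = 0.559 with an estimated correlation), H2-Aa rising by 1.61 and Cd74 by 1.09. The camera p of this list was 0.0503 without 24-hour replicate 2, 0.0719 without 24-hour replicate 3 and 0.0524 without 7-day replicate 1, and 3 of its genes rose without 24-hour replicate 1, 2 or 3 or 7-day replicate 1. Endothelial markers rose in 4 of 14 cases and fell in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0190, and adjusted p = 0.231 with an estimated correlation), Cldn5 by 0.46, and 2 rose without 24-hour replicate 1 or 2 or 7-day replicate 1. With an estimated correlation camera called none of the 111 tests of the 3 comparisons.

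In all, limma called 2009 of 19938 genes between 24 hours and 7 days, 1050 higher and 959 lower at 7 days, and 125 of them differed at least 2-fold (85 higher, 40 lower). With each array centred on its median the same comparison gave 888 higher and 1247 lower. The total was 1283 without 24-hour replicate 1, 1158 without 24-hour replicate 2 and 1149 without 7-day replicate 3. It was 516 without the pair of 7-day replicates that carried brown fat transcripts, which leaves 1 array at that age.

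The second comparison asks what changed between the first week and adulthood. Tnni1 (probe set 10350149), the troponin I of the fetal heart, fell by 6.00 on the log2 scale between 7 days and 10 weeks, from 11.09 ± 0.08 to 5.09 ± 0.21 (SD, n = 3; adjusted p = 2.77e-10). Every one of 29 mitosis genes fell, with cyclin A2 (Ccna2) going from 9.22 ± 0.02 to 5.07 ± 0.41, and 30 of 33 extracellular matrix genes fell, with the elastin gene Eln going from 10.47 ± 0.89 to 6.34 ± 0.04. Of 19 antigen presentation and interferon genes 18 rose, led by the MHC class II gene H2-Aa (probe set 10450154), which rose 17.4-fold from 6.09 ± 0.02 to 10.22 ± 0.39. Of 25 mature cardiomyocyte genes 16 rose, and so did Bdh1, which encodes an enzyme of ketone body use, from 4.47 ± 0.19 to 8.25 ± 0.23. Myh7 rose again by 1.85 to 11.01 ± 0.13, and Myh6 measured 12.64 ± 0.02 at 10 weeks (adjusted p = 0.207 against 7 days).

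The largest rise was that of Myot, which encodes the Z-disc protein myotilin, by 4.51 ± 0.14 (SE, adjusted p = 1.42e-08). It was followed by the interferon-inducible gene Ifi205 (4.38), BC023105 (4.25), H2-Aa (4.12), the invariant chain gene Cd74 (3.81), Bdh1 (3.78), H2-Ab1 (3.70) and the xanthine dehydrogenase gene Xdh (3.60). BC023105 measured 8.77, 6.89 and 9.98 on the 10-week replicates and at most 4.38 on a 7-day one. The largest falls after Tnni1 were those of the atrial growth factor gene Bmp10 (by 5.30 on the log2 scale), the potassium channel subunit gene Kcne1 (by 4.38) and the imprinted gene Mest (by 4.38). Ucp1 followed with a difference of -4.18 (adjusted p = 0.0283), Myl7 fell by 4.16, Ccna2 by 4.15 and Eln by 4.13. Of the atrial genes, Myl7 measured 4.70, 8.43 and 7.52 on the 10-week replicates and Bmp10 4.42, 4.57 and 4.29. The Ucp1 difference rests on 2 of the 7-day arrays. It was -2.70 without 7-day replicate 2, -3.68 without 7-day replicate 3, -4.09, -4.25 and -4.19 without 10-week replicate 1, 2 or 3, and none of these passed the test, nor did it with a robust variance prior (adjusted p = 0.0966) or with only the 6 arrays compared (0.0807).

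Mitosis genes fell in 29 of 29 cases, and in 29 when adjusted over the list alone (camera adjusted p = 9.31e-26, and adjusted p = 0.174 with an estimated correlation). The spindle gene Prc1 fell by 3.86 on the log2 scale, Mki67 by 3.58 and the topoisomerase gene Top2a fell by 3.56. DNA replication genes fell in 30 of 30 cases, both over all genes and adjusted over the list alone (camera adjusted p = 3.21e-18, and adjusted p = 0.177 with an estimated correlation). The primase gene Prim1 fell by 2.23 on the log2 scale, Mcm6 by 2.15 and Rrm2 by 2.12. Of 16 cell cycle inhibitors 4 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.314), with Gadd45a rising by 1.05 and Rbl1 falling by 1.31. Imprinted and fetal growth genes fell in 15 of 19 cases and rose in none (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.6e-10, and adjusted p = 0.0879 with an estimated correlation). Among them Slc38a4 fell by 3.60, Igf2 by 3.48 and Plagl1 by 3.36. The Y-linked gene Eif2s3y fell by 3.54 on the log2 scale between the same ages, and Uty went from 5.75 ± 0.78 to 3.25 ± 0.08.

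Of 33 extracellular matrix genes 30 fell and 1 rose, both over all genes and adjusted over the list alone (camera adjusted p = 2.0e-20, and adjusted p = 0.205 with an estimated correlation). The crosslinking enzyme gene Lox fell by 3.27, Tnc by 3.26, Col1a1 by 3.02 and Postn, which encodes periostin, by 2.45. Fibroblast markers fell in 10 of 15 cases and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 2.49e-05, and adjusted p = 0.280 with an estimated correlation). The 1 that rose was Gsn, which encodes the actin-severing protein gelsolin, by 1.64. Of 11 markers of epicardium and mesothelium 9 fell and none rose (9 adjusted over the list alone; camera adjusted p = 7.06e-06, and adjusted p = 0.231 with an estimated correlation), Aldh1a2 by 2.13 and Upk3b by 1.64. Mural markers rose in 3 and fell in 4 of 10 cases (3 and 4 adjusted over the list alone; camera adjusted p = 0.747), with a median of 0.10 and a mean of -0.11. Without 7-day replicates 2 and 3, which carried brown fat transcripts, the matrix list had 28 lower and 1 higher and a median of -1.31. Of 7 brown fat genes 4 were lower at 10 weeks (4 adjusted over the list alone; camera adjusted p = 0.0370, and adjusted p = 0.407 with an estimated correlation), but 2 without 7-day replicate 2, 7-day replicate 3, 10-week replicate 1 or 10-week replicate 2. The camera p of this list was 0.102 without 7-day replicate 2, 0.0531 without 10-week replicate 1 and 0.0592 without 10-week replicate 2.

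Antigen presentation and interferon genes rose in 18 of 19 cases (18 adjusted over the list alone; camera adjusted p = 1.47e-12, and adjusted p = 0.174 with an estimated correlation). The interferon-induced gene Ifit1 rose by 2.87, and the only member that did not pass was Nlrc5, an activator of MHC class I genes looked up after the values were seen, at 8.13 and 8.29. Macrophage markers rose in 13 of 15 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 1.36e-06, and adjusted p = 0.174 with an estimated correlation). Lyz2 rose by 1.82, F13a1 by 1.60 and the scavenger receptor gene Cd163 by 1.51; the 1 marker that was lower, the chemokine receptor gene Cx3cr1, was looked up after the values were seen. It went from 6.40 to 6.11, and without 7-day replicate 3 the list had 0 markers lower. Endothelial markers went both ways, with 2 of 14 higher and 6 lower (2 and 6 adjusted over the list alone; camera adjusted p = 0.203), Flt1 rising by 0.86 and the tight junction gene Cldn5 falling by 0.95.

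Mature cardiomyocyte genes rose in 16 of 25 cases and fell in 1 (18 and 2 adjusted over the list alone; camera adjusted p = 1.99e-04, and adjusted p = 0.245 with an estimated correlation). The Z-disc gene Tcap rose by 1.88, Hrc by 1.36 and Ckmt2 by 1.24. Of 20 immature cardiomyocyte genes 13 fell and 4 rose (15 and 4 adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.245 with an estimated correlation). The smooth muscle light chain Myl9 fell by 2.28, while Acta1, the skeletal alpha-actin, rose by 2.02 and the natriuretic peptide gene Nppb by 1.17. Of 11 atrial genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00761, and adjusted p = 0.456 with an estimated correlation), and the 10-week replicates differed widely in Myl7 and in Myl4, which measured 6.43, 9.77 and 8.83. Without the 50% of genes with the lowest signal the camera p of the atrial list was 0.0794. Without 7-day replicates 2 and 3 the median of the immature list went from -0.94 to -0.57. That of the atrial list went from -1.46 to -1.17, and that of the mature list from 0.27 to 0.30. Myl4 fell by 3.15 and Mybphl by 2.07. Both also belong to the immature list, as does Myl7. Of the 11 atrial genes, 9 were higher on 10-week replicate 2 than on replicate 1, and 10 were higher on replicate 3. A difference in atrial tissue between arrays was not told apart from age for the atrial falls. Cardiac transcription factors fell in 9 of 20 cases and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00131, and adjusted p = 0.174 with an estimated correlation), Hey2 by 1.49, Tbx20 by 1.11 and Gata6 by 0.97. None rose when 7-day replicate 2, 7-day replicate 3 or 10-week replicate 2 was left out.

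Oxidative phosphorylation genes rose in 23 of 42 cases and fell in 1 (24 and 1 adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.598 with an estimated correlation), by small amounts with a list mean of 0.16. The complex I subunit gene Ndufb3 rose by 0.74 and Ndufa5 by 0.54, while Cox8a fell by 0.55. Without 7-day replicates 2 and 3 the list median went from 0.185 to 0.149. Of 18 genes of the TCA cycle 10 rose and none fell (10 adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.244 with an estimated correlation), the pyruvate carrier gene Mpc1 by 0.83 and Suclg2 by 0.73. Fatty acid oxidation genes went both ways, with 13 of 27 higher and 8 lower (14 and 8 adjusted over the list alone; camera adjusted p = 0.330), a median above 0 and a mean of -0.003. The lipoprotein lipase gene Lpl rose by 0.97 and Echs1 by 0.66, while Angptl4, which inhibits Lpl, fell by 2.67 and Pdk4 by 0.98. Among 21 glycolysis genes 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.451), with Pfkfb2 rising by 1.99 and Hk2 by 1.39. The insulin-responsive glucose transporter gene Slc2a4 rose by 1.41 and Slc2a1 by 0.59. Among 19 metabolic transcription factors 11 rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0521), with Rxrg rising by 1.62, Klf15 by 1.49, the thyroid hormone receptor gene Thrb by 1.20 and Ppara by 0.55.

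**Figure D3:**
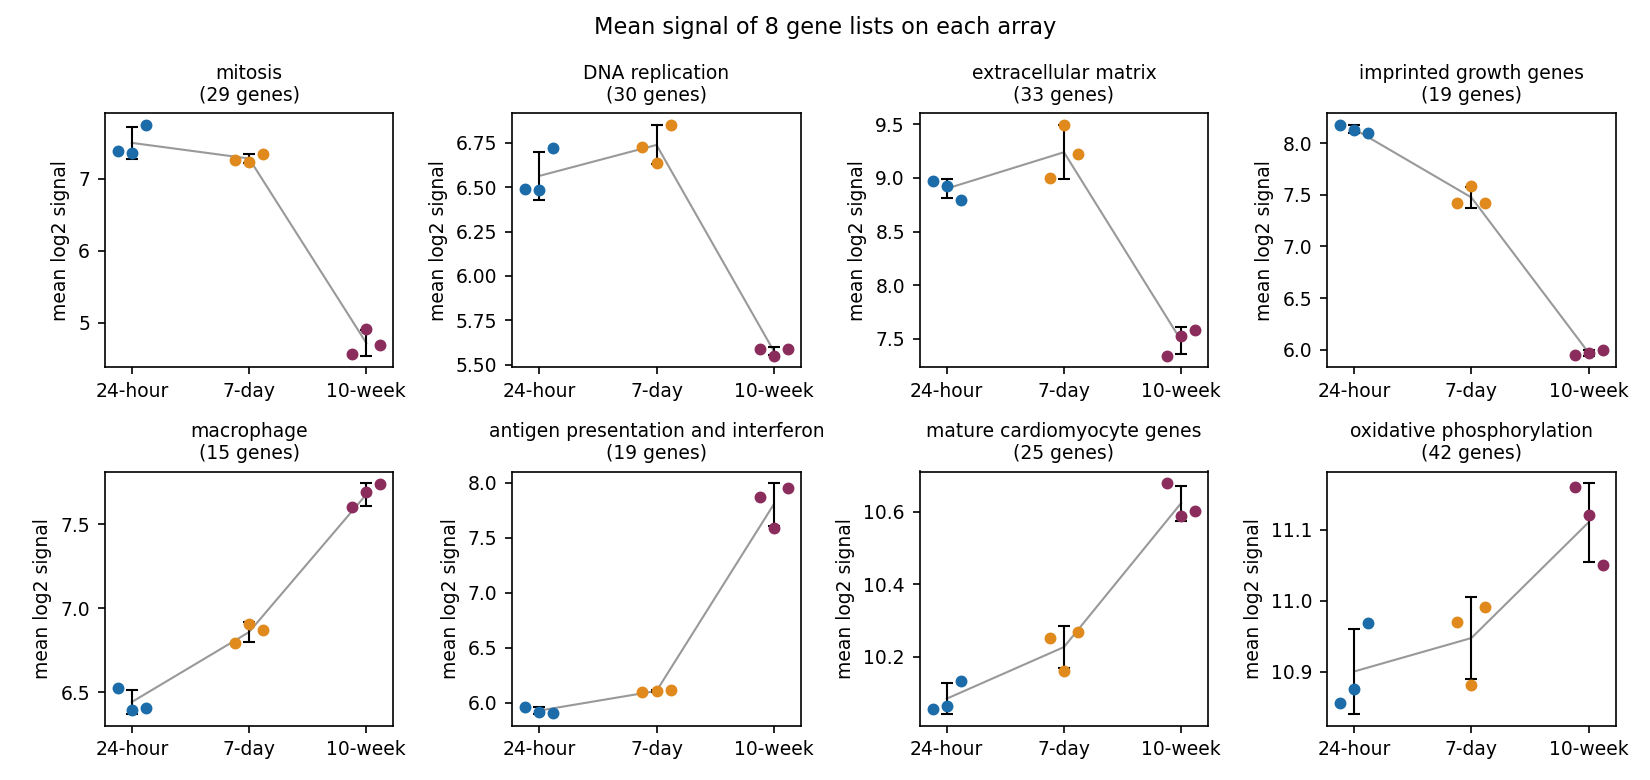
Mean log2 signal (vertical axes) of the tested members of 8 gene lists at the 3 ages (horizontal axes). Points are single arrays, black bars the mean ± SD (n = 3), and grey lines join the means; the mitosis list lay at 7.23 to 7.75 on the 24-hour and 7-day arrays and at 4.56 to 4.91 on the 10-week arrays, and each vertical axis has its own range.

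In all, limma called 7165 of 19938 genes between 7 days and 10 weeks, 3388 higher and 3777 lower at 10 weeks, and 1006 of them differed at least 2-fold (412 higher, 594 lower). With each array centred on its median, which moved the median of all genes from 0.04 to 0.10, the calls were 5247 higher and 3307 lower. The total was 4156 without 7-day replicates 2 and 3.

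The third comparison spans the whole interval from 24 hours to 10 weeks. Tnni1 fell by 6.71 on the log2 scale, from 11.81 ± 0.06 to 5.09 ± 0.21 (SD, n = 3; adjusted p = 8.80e-11). Mest fell by 5.13 and Plagl1 by 4.59 on the log2 scale, and Igf2 was 18.3-fold lower. H2-Aa rose by 5.73, from 4.49 ± 0.16 to 10.22 ± 0.39, and AW112010, a gene whose function is not given in the sources used here, rose from 3.51 ± 0.01 to 8.52 ± 0.12. Myh7 ended 1.24 lower than it began, Myh6 differed by -0.14 (adjusted p = 0.0152, and not past the test without 24-hour replicate 3, also at -0.14), and Tnni3, the adult troponin I, rose by 0.29.

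Further rises were those of Myot (4.97), Cd74 (4.90), Ifi205 (4.57), the actin-binding Xin repeat gene Xirp2 (4.40), BC023105 (4.37) and H2-Ab1 (4.35). Further falls, on the log2 scale, were those of Capn6 (fell by 5.14), Ddc, which encodes an amino acid decarboxylase (from 9.40 to 4.40), Ccna2 (fell by 4.34), the adhesion molecule gene Ncam1 (fell by 4.31) and Tmem255a (from 8.88 to 4.68). Mitosis genes fell in 29 of 29 cases (29 adjusted over the list alone; camera adjusted p = 2.63e-24, and adjusted p = 0.174 with an estimated correlation). Extracellular matrix genes fell in 28 of 33 and rose in 3 (28 and 3 adjusted over the list alone; camera adjusted p = 1.0e-12, and adjusted p = 0.250 with an estimated correlation), with Fbn2 falling by 3.51 and Fn1, which encodes fibronectin, by 3.12. Imprinted and fetal growth genes fell in 16 of 19 cases (16 adjusted over the list alone, camera adjusted p = 4.21e-13, and adjusted p = 0.0595 with an estimated correlation). Macrophage markers rose in 12 of 15 (12 adjusted over the list alone; camera adjusted p = 8.53e-08, and adjusted p = 0.142 with an estimated correlation). Among the mature cardiomyocyte genes 15 of 25 rose and 6 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.294 with an estimated correlation). DNA replication genes fell in 28 of 30 cases (29 adjusted over the list alone; camera adjusted p = 7.28e-14, and adjusted p = 0.216 with an estimated correlation), and antigen presentation and interferon genes rose in 18 of 19 (18 adjusted over the list alone; camera adjusted p = 1.65e-11, and adjusted p = 0.174 with an estimated correlation). Immature cardiomyocyte genes fell in 15 of 20 and rose in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 2.56e-05, and adjusted p = 0.205 with an estimated correlation). Cardiac transcription factors fell in 13 of 20 (14 adjusted over the list alone; camera adjusted p = 1.56e-06, and adjusted p = 0.124 with an estimated correlation). Epicardial and mesothelial markers fell in 9 of 11 (10 adjusted over the list alone; camera adjusted p = 1.11e-05, and adjusted p = 0.231 with an estimated correlation). Antioxidant genes rose in 13 of 23 and fell in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.231 with an estimated correlation). Fibroblast markers rose in 6 and fell in 6 of 15 cases (6 and 6 adjusted over the list alone; camera adjusted p = 0.633), with a median of 0.06 and a mean of -0.26. Oxidative phosphorylation genes rose in 25 of 42 cases and fell in 3 (26 and 4 adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.592 with an estimated correlation), and 16 rose without 24-hour replicate 1. Eif2s3y and Uty were 3.92 and 2.92 lower (log2 differences of -3.92 and -2.92) in the same arrays. The total called was 7989 genes, 3878 higher and 4111 lower at 10 weeks, with 1273 changed at least 2-fold (598 higher, 675 lower). With each array centred on its median the calls were 4551 higher and 3834 lower.

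Crossing both steps shows the course of each gene over the 3 ages. Higher in both steps were 404 genes, led by Scgb1c1, which went from 6.07 ± 0.28 to 8.22 ± 0.46 and 10.36 ± 0.22 (SD, n = 3), Xirp2, Tuba8, AW112010 and Lrtm1. Lower in both steps were 417 genes. A rise followed by a fall was called for 359 genes. Ccn3 went from 7.35 ± 0.17 to 9.02 ± 0.27 and 5.74 ± 0.22, and Fap, the fibroblast activation protein gene, from 4.75 ± 0.15 to 6.74 ± 0.15 and 5.18 ± 0.07. Sbk3, Osr1 and Bmp10 took the same course, but the first-week call of Osr1 was not made without 24-hour replicate 2 (1.65) or 24-hour replicate 3 (1.25) or with only the 6 arrays compared (adjusted p = 0.0731), nor that of Bmp10 without 7-day replicate 3 (1.30). A fall followed by a rise was called for 246 genes, with Myh7 the largest and the metalloproteinase inhibitor gene Timp4 next, at 6.69 ± 0.07, 5.33 ± 0.30 and 7.95 ± 0.23. Kyat3 and the glutathione transferase gene Gstm1 did the same, and so did Serpina3n, whose first-week difference of -1.02 did not pass without 24-hour replicate 1 (-1.01), 2 (-0.93) or 3 (-1.13), 7-day replicate 1 (-1.01) or 3 (-0.87), or 10-week replicate 2 (-1.02), nor with a replicate block (adjusted p = 0.0633) or a robust variance prior (0.0515). Most calls belonged to the later step alone, with 2738 genes higher and 3001 lower only after the first week (3046.6 and 3396.4 for independent lists), against 287 and 296 in the first week only (672.7 and 614.4).

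Independent lists of these sizes would share 178.4 genes higher in both steps, 181.7 lower in both, 198.9 higher then lower and 163.0 lower then higher. Both steps use the 7-day arrays, and in 100 simulations with no change between ages limma called no gene in both steps (at an unadjusted p under 0.05, 4.86 genes moved the same way and 260.8 opposite ways on average). Part of the excess of turning genes over independent lists may come from those shared arrays, which are too few to divide into parts of at least 2. Calls also depended on signal. In the first week 0.20% of the 25% of genes with the lowest signal were higher, against 10.61% of the highest 25%. After it 0.72% and 36.45% were lower. Independent lists over all genes can thus be too low a benchmark for all 4 courses. The numbers of genes higher in both steps, lower in both, higher then lower and lower then higher were 262, 263, 188 and 120 without 24-hour replicate 2 and 226, 239, 195 and 147 without 7-day replicate 3. Without 7-day replicate 1 the genes higher in both, lower in both and lower then higher numbered 268, 262 and 160, and without 24-hour replicate 3 the genes lower in both, higher then lower and lower then higher numbered 273, 235 and 148. Without 24-hour replicate 1 the turning genes numbered 223 and 149.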

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

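Both results here lie in features outside the tested genes, and the comparison of these features was chosen only after the values were seen. Features absent from the platform table and those with several gene symbols were fitted together, apart from the features with a single symbol. The p-values were adjusted over the features of that fit only. Of 12146 features absent from the platform table, limma called 621 higher and 732 lower at 10 weeks than at 24 hours. Among these calls, 98 and 171 differed at least 2-fold. Of 1621 features with several gene symbols, 162 were higher and 289 lower. These features were singled out because they carry differences between the ages that the comparisons of named genes do not use. The features off the platform table have no gene name in the sources used here, so no function can be given for them.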

How the results depend on the processing

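A fit of all 35556 features called 1724, 9006 and 10351 features in the 3 comparisons. This fit, the set test fry and the fit without 7-day replicates 2 and 3 were chosen only after the data were seen. That last fit leaves 1 array at 7 days, which is assumed to vary like the other groups.

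The fall of mitosis and matrix genes and the rise of antigen presentation genes after the first week were called in every setting in which set tests were run, fry included, except camera with an estimated correlation, while first-week and time course counts moved more than later ones. Of 9276 values of the named genes under alternatives, 8837 gave the same call, 419 a weaker one, 20 a stronger one and 0 a reversed direction. The genes changed between 24 hours and 7 days (2009) numbered 3367 with array weights, 953 at adjusted p under 0.01, and 516 with 7-day replicates 2 and 3 left out. With those arrays left out the genes changed between 7 days and 10 weeks (7165) numbered 4156. In the first week the list medians were then 0.107 for antigen presentation and interferon, 0.145 for endothelial markers and 0.183 for mature cardiomyocyte genes. With all arrays they were 0.138, 0.173 and 0.147. Leaving out 1 array gave 1149 to 2316 genes for the first comparison, 6124 to 7275 for the second and 6772 to 8085 for the last; at least 2-fold changed 111 to 143, 966 to 1037 and 1250 to 1305. The lowest first-week counts were 1149 without 7-day replicate 3, 1158 without 24-hour replicate 2 and 1283 without 24-hour replicate 1. Quantile normalization gave 2089, 7057 and 7656 genes. With only the 6 arrays compared, which takes the spread from those 6 alone, the counts were 2298, 6262 and 7315. Centring each array on its median changed the share of calls that were higher from 52.3% to 41.6% in the first comparison and from 47.3% to 61.3% in the second. Of the 25% of genes with the lowest signal, 413 were higher and 36 lower at 10 weeks than at 7 days, against 1262 and 1817 of the 25% with the highest.

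Time course counts moved with the settings too. Genes higher in both steps (404) numbered 92 with 7-day replicates 2 and 3 left out and 199 at adjusted p under 0.01; lower in both (417), 706 with array weights, 104 with 7-day replicates 2 and 3 left out and 203 at adjusted p under 0.01. Genes higher then lower (359) numbered 564 with array weights, 78 with 7-day replicates 2 and 3 left out and 154 at adjusted p under 0.01; lower then higher (246), 374 with arrays centred on their medians, 62 with 7-day replicates 2 and 3 left out and 91 at adjusted p under 0.01. Genes higher in the first week only (287) numbered 537 with array weights, 95 with 7-day replicates 2 and 3 left out and 163 at adjusted p under 0.01; lower in the first week only (296), 616, 85 and 143 in the same settings. Genes higher after the first week only (2738) numbered 4494 with arrays centred on their medians, 1706 without the 50% of genes with the lowest signal and 1711 with 7-day replicates 2 and 3 left out. Leaving out 1 array gave 226 to 444 higher in both, 239 to 541 lower in both, 188 to 387 higher then lower, 120 to 261 lower then higher, 161 to 329 and 164 to 354 in the first week only, and 2292 to 2804 and 2675 to 3146 after it only. The first-week-only counts fell to 174 and 174 without 24-hour replicate 1, 161 and 164 without 24-hour replicate 2, and 172 and 170 without 7-day replicate 3; those lower in the first week only were 183 without 24-hour replicate 3 and 182 without 7-day replicate 1.

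Camera called 50 of 111 set tests, 48 to 55 when 1 array was left out, 56 with quantile normalization, 47 of 105 without the 25% of genes with the lowest signal and 42 of 78 without the lowest 50%; with an estimated correlation it called 0 (smallest adjusted p 0.0595), and fry called 69. Among the first-week calls, camera without the 25% of genes with the lowest signal gave adjusted p = 0.0605 for antigen presentation and interferon and 0.0538 for brown fat, and without the lowest 50% 0.231 for glycolysis; brown fat after the first week had 0.0939 without the lowest 25%. In the first week fry gave adjusted p = 0.203 for mitosis, 0.0542 for extracellular matrix and 0.0956 for DNA replication. It gave 0.0991 for antigen presentation and interferon and 0.0736 for brown fat. A replicate block gave 1734, 6916 and 7724 genes. Residuals of arrays with the same replicate number correlated at -0.174 to 0.133, against -0.216 to 0.250 for other pairs, so the numbers were not treated as pairs. A pseudocount was not run, since the values are already log2.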

Other observations

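Tests of Y-linked levels, of slopes for imprinted and DNA replication genes and of slopes with Kdm5d were chosen only after the results were seen. So were those of a share over 25% of the falls, of macrophages and B cells and of the other splits of the arrays. For mitosis and the extracellular matrix, the slopes and the limit of 25% on a whole source were set before. Circadian clock genes rose in 9 of 16 cases and fell in 3 between 7 days and 10 weeks (9 and 4 adjusted over the list alone; camera adjusted p = 0.0318, and adjusted p = 0.196 with an estimated correlation), with the clock repressor gene Nr1d1 rising by 1.93 and Dbp by 1.19. The camera p of this list was 0.0664 without 10-week replicate 3 and 0.0678 with arrays centred on their medians. Antioxidant genes rose in 12 of 23 cases and fell in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.216 with an estimated correlation), Gstm1 by 2.24 and the quinone reductase gene Nqo1 by 2.01. Over the whole span, ribosome biogenesis genes fell in 12 of 20 cases and rose in 1 between 24 hours and 10 weeks (12 and 1 adjusted over the list alone; camera adjusted p = 0.00156, adjusted p = 0.136 with an estimated correlation, and 0.0583 without the 50% of genes with the lowest signal). In the first week 3 of them fell (4 adjusted over the list alone; camera adjusted p = 0.00240, and adjusted p = 0.142 with an estimated correlation), 1 without 24-hour replicate 1 or 2. Splicing regulators fell in 8 of 14 cases and rose in 3 between 24 hours and 10 weeks (8 and 3 adjusted over the list alone; camera adjusted p = 0.0318, and adjusted p = 0.294 with an estimated correlation). The camera p of the splicing list was 0.0975 without the 25% of genes with the lowest signal and 0.370 without the lowest 50%. Hippo YAP targets rose in 3 and fell in 5 of 18 cases after the first week (3 and 5 adjusted over the list alone; camera adjusted p = 0.666), and 3 fell without 24-hour replicate 1, 7-day replicate 2 or 10-week replicate 1 or 2.

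T cell markers were higher in 7 of 10 cases at 10 weeks than at 24 hours (7 adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.174 with an estimated correlation), but 4 without 24-hour replicate 3. In the first week 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.0286, adjusted p = 0.196 with an estimated correlation, 0.0784 without 24-hour replicate 3 and 0.0588 without 7-day replicate 3). Of 11 neutrophil markers 1 was lower in the first week (1 adjusted over the list alone; camera adjusted p = 0.0286, adjusted p = 0.196 with an estimated correlation, 0.0719 without 7-day replicate 2 and 0.0939 without the 25% of genes with the lowest signal). Glia and nerve markers were higher in 4 of 8 cases at 10 weeks than at 24 hours (5 adjusted over the list alone; camera adjusted p = 0.0211, adjusted p = 0.231 with an estimated correlation, and 0.0939 without the 25% of genes with the lowest signal), Mal by 1.84. Between 24 hours and 10 weeks B cell markers were higher in 1 of 8 cases (camera adjusted p = 0.255), neutrophil markers higher in 1 and lower in 2 of 11 (0.673), and erythroid markers lower in 3 of 10 (0.207). Thymocyte markers were higher in 2 and lower in 3 of 8 cases (0.744), with a median of 0.06 and a mean of -0.31. Ventricle genes were higher in 1 and lower in 3 of 7 cases (0.305), skeletal muscle genes lower in 1 of 14 (0.965), lung genes higher in 1 of 9 (0.521), liver and plasma protein genes lower in 1 of 9 (0.673) and white fat genes higher in 2 of 7 (0.146). Counts of 1 to 3 such markers often moved by 1 or 2 when an array was left out.

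The 10-week arrays lack Y-linked transcripts that the younger arrays hold. The highest 10-week array median over the 3 tested Y-linked genes was 3.34, below the lower quartile of that array's genes, while Xist lay at 8.69 to 8.97, so the 10-week samples may hold no male tissue. Missing male tissue as the whole source of later falls was tested for 4 lists. Within the younger groups the slope of the list mean on the mean of Eif2s3y and Uty was -0.139 for mitosis (95% limits -0.417 and 0.138, needed slope 0.847), -0.086 for the extracellular matrix (-0.498 and 0.326, needed 0.580), -0.016 for imprinted growth genes (-0.192 and 0.160, needed 0.497) and -0.090 for DNA replication (-0.326 and 0.146, needed 0.384). The limit set for arguing against a whole source was an upper limit below 25% of the needed slope. Mitosis met it (0.212, and with Kdm5d added an upper limit of 0.144 against 0.277), and the others did not (0.145, 0.124 and 0.096). The needed slope divides by a Y-linked change of -3.02, which ends at dim signals and can be too small. The needed slopes can therefore be too high. A whole source is thus argued against for mitosis alone, with an upper limit of 0.138 against 0.847, and stays open for the others. A share over 25% stays open for all 4 lists. These slopes come from the 6 younger arrays and do not measure sex in adult hearts. Sex itself was not tested as a difference between ages, and other effects of sex stay open.

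Of the MHC class II pathway, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 rose more than macrophage markers after the first week. The smallest rise of these 4 class II genes, 2.76 for H2-Eb1, exceeded the largest of 15 macrophage markers, 1.82 for Lyz2, by 0.94 ± 0.16 (SE). The 4 genes were picked after the values were seen, and H2-Aa, Cd74 and H2-Ab1 were among the 8 largest rises. H2-DMa and Ciita of the same list were not compared, and the SE takes 2 genes picked as extremes to be independent. The gap therefore cannot decide whether more macrophages with an unchanged class II level in each are the whole source. Of 8 B cell markers limma called 0 after the first week (2 at an unadjusted p under 0.05), with a median rise of 0.095, but all 8 lay below the median signal, where a rise can be missed, so B cells stay open. Other class II-positive cells, a higher level per macrophage, and age or sex as such stay open too and were not tested.

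Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split called 2009, 7165 and 7989 genes and the highest other split 1, 0 and 0; at least 2-fold these were 125, 1006 and 1273 against 1, 0 and 0; and for lists 17, 17 and 16 against 14, 16 and 14. In each case 1 of the 10 splits, the real one, gave a value as large. For time courses 100 groupings of the 9 arrays were drawn. The 821 genes that moved the same way in both steps were matched by 1 of 100, the real one. The next gave 252, with the ages in another order. For the 605 that turned, 3 of 100 gave a count as large. The others were 1 with the ages in another order (1370) and 1 in which a single group was of 1 age (5338), so they point to a structure of the samples; other groupings with a single group of 1 age gave 0 or 5. Groupings that mix ages widen the spread within groups. These shares therefore do not say whether chance can be excluded, for the genes that moved the same way or for those that turned.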
